A study of Mus musculus with 12 samples.

How the data were processed

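RNA was measured by sequencing of total RNA from the medial prefrontal cortex (mPFC) of mice. The 12 libraries form 4 groups of 3: C57 mice given the DMSO solvent control (C57 vehicle), C57 mice given astragaloside IV (C57 ASIV), BTBR mice given DMSO (BTBR vehicle) and BTBR mice given astragaloside IV (BTBR ASIV). Injections were intraperitoneal and lasted 7 days. RNA was extracted with Trizol and libraries were made by standard Illumina protocols, per the labels.

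The deposited gene table holds FPKM (fragments per kilobase of gene, scaled to the depth of the library) as computed by the authors, with 1 column per library and 17283 genes. The labels name HISAT2 2.0.5 and the mm10 genome; the counter, the annotation, the strand of counting and any filter are not given in the sources used here. No gene of the table is 0 in any of the 12 libraries, and the table has 0 other columns. Gene identifiers were looked up in GENCODE M21: 17265 matched and took symbol, position and class from it, and 18 did not. In the table, 6 symbols belong to more than 1 identifier, so a list can hold more tested entries than symbols.

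After multiplication by the exon length of GENCODE M21, the low values of each library are whole multiples of 1 step, which gives the depth in the denominator. Of the values under 50 fragments, 97.6 to 98.0% were whole within 0.02, and of all values 95.7 to 95.8%. The depth found in this way was 16166328 to 18660039 fragments per library, so that 1 fragment on a gene of 1 kb equals 0.0536 to 0.0619 FPKM. Replicates differed by more than counting error, with a chi-square per gene of 7.57 to 43.13 for genes with at least 20 fragments. Pearson correlations between replicates on the log2 scale ran from 0.979 to 0.994.

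Values were analysed as log2(FPKM + 1). Genes with FPKM of at least 1 in 3 or more of the 12 libraries were tested (13586 genes). A linear model with 4 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust options, 8 residual degrees of freedom), and p-values were adjusted by Benjamini-Hochberg over the genes tested. A gene was called at an adjusted p under 0.05. The 5 comparisons were the strains under vehicle, the strains under ASIV, ASIV in BTBR, ASIV in C57, and the interaction of strain and ASIV. Log2 differences carry the standard error of the model, and a fold is that of FPKM + 1. Levels are means with the standard deviation over 3 libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the table and drew the plots.

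The tests, the gene lists and the alternatives were fixed before the data were examined. Genes were named by this rule, per comparison: the 10 higher and the 10 lower with the largest absolute log2 difference among called genes whose groups do not overlap. Where fewer passed, up to 5 per direction with the smallest p were given as values that did not pass. Symbols that start with Gm and a number, end in Rik or contain -ps were left out of the naming. For the interaction the rule took the 5 genes with the smallest p. Up to 4 members with the smallest p were named for each list, and Camk2n2, Camk2n1, Camk2a, Camk2b and tested genes of the BTBR background loci were always named. RNAs of the mitochondrial genome filled much of the rule, so it was repeated on nuclear protein-coding genes and for the strains under ASIV, a choice made after seeing the data. Some genes that the rule names are not reported here.

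Of 44 gene lists, 43 had at least 3 tested members. The list of BTBR background loci had 1 tested member, Itpr3. Lists were tested with limma camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 43 lists, and again with a correlation estimated per list. Camera compares a list with the other genes; fry, also run, tests it against no change. Counts of members are given over all genes and, where they differ, adjusted over the list alone. For Camk2n2 an exact two-sided permutation test was added, which with 3 against 3 libraries cannot go below p = 0.1. Correlations between comparisons are Pearson's r across genes, without a p because genes are not independent replicates. Simulations of unchanged groups (100) gave the value that shared libraries produce. A further 100, added after seeing the data, used the spread of each group. Both sets drew genes independently.

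The pipeline was tested on simulated data with a spread per expression level pooled over the 4 groups and with independent genes. With 3 libraries per group it recovered 39.4, 86.4 and 96.9% of genes changed 1.5, 2 and 4 times in ASIV against vehicle in BTBR. There were 11 false calls among 13257 unchanged genes. The real BTBR vehicle libraries varied more than the C57 vehicle ones (mean variance 0.0642 and 0.0226), so these rates may not hold for BTBR.

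Alternatives covered the pseudocount (0.1), the filter (none, or FPKM of at least 5), scaling (each library rescaled to TPM, median ratio, quantile normalization), a fit on only the 2 groups compared, the replicate number as a block, library weights and leaving out each library. Voom had been planned for a table that gives gene lengths, which this one does not; it was run on the recovered fragments instead. That fit, removal of a GC and length trend, and rescaling without genes of the mitochondrial genome were chosen after seeing the data. For matches between genes, the share of 31-base words in common with other annotated genes was used. The labels give no library batch, so none could be added to the model. Nothing in the labels says whether the 3 libraries of a group come from separate animals, so each p measures only the spread between these libraries.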

Results

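Gene expression in the mPFC was compared between C57 mice, used as the reference strain, and BTBR mice, an inbred strain used as a model of autism. Each strain was given either DMSO vehicle or astragaloside IV (ASIV), a saponin of Astragalus root, for 7 days. The stated aim was to learn whether ASIV improves neurotransmitter transmission in BTBR mice, and the series title names Camk2n2, oxidative phosphorylation (OXPHOS) and neurotransmission. Each of the 4 groups held 3 libraries of 16166328 to 18660039 fragments, and 13586 genes were tested. The first principal component held 54% of the variance and set the BTBR vehicle libraries (36.9 to 47.8) apart from the BTBR ASIV (-4.1 to 2.3) and C57 libraries (-23.7 to -13.8).

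The mRNAs of the mitochondrial genome, which encode core subunits of the respiratory complexes and of ATP synthase, made up 4.62 ± 0.183% of fragments in C57 vehicle (SD, n = 3). They made up 3.98 ± 0.911% in C57 ASIV, 0.457 ± 0.161% in BTBR vehicle and 3.12 ± 0.101% in BTBR ASIV. The 2 mitochondrial ribosomal RNAs together held 0.537 ± 0.029%, 0.573 ± 0.059%, 0.410 ± 0.128% and 0.770 ± 0.147% in the same order.

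**Figure D1:**
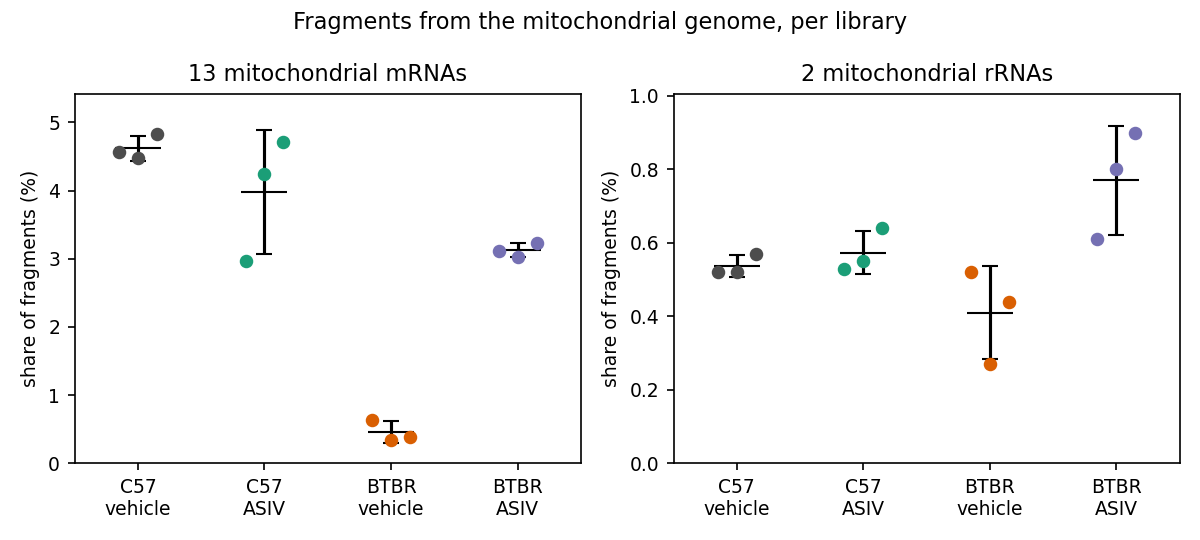
Share of sequenced fragments (percent) from mRNAs and from ribosomal RNAs of the mitochondrial genome, per library, in the 4 groups. Points are libraries, and bars give the mean and SD of 3 libraries. The mRNA share averaged 0.457% in BTBR vehicle, against 3.12% in BTBR ASIV and 4.62% in C57 vehicle.

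The comparison of BTBR with C57 under vehicle asked how the model strain differs from the reference strain. All 13 mRNAs of the mitochondrial genome were lower in BTBR, with a median log2 difference of -4.38. mt-Nd4, a subunit of complex I (mitochondrial genome, positions 10167 to 11544, mm10), had 2195 ± 87.5 FPKM in C57 vehicle and 83.5 ± 16.1 in BTBR vehicle. Its log2 difference was -4.72 ± 0.27 (SE, adjusted p = 5.98e-07). mt-Nd2 stood at -4.44 ± 0.22, mt-Cytb, the cytochrome b of complex III, at -4.49 ± 0.27, and mt-Nd3 at -5.49 ± 0.26. The differences were smaller for mt-Nd5 (-2.65 ± 0.15) and for mt-Nd6 (-1.29), the 1 mRNA of the other strand. Mitochondrial transfer RNAs such as mt-Te (-5.78 ± 0.29) and mt-Tc (-4.92 ± 0.37) were also lower. Such short genes can lie beside mRNAs, as mt-Te (14071 to 14139) does beside mt-Cytb (from 14145). Whether their counts are separate from those of the mRNAs was not tested. Of the ribosomal RNAs, mt-Rnr1 was lower (-0.79, adjusted p = 0.0153) and mt-Rnr2 stood at -0.22 (adjusted p = 0.402). mt-Nd6 and the ribosomal RNAs were chosen after their values were seen. As a list, the mitochondrial mRNAs were called lower (camera, adjusted p = 9.12e-13), with 13 of 13 called over all genes and 13 adjusted over the list alone. The adjusted p was 0.611 with an estimated correlation.

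Nuclear genes of OXPHOS went both ways under vehicle. Of 36 complex I subunits, 14 were higher and 17 lower in BTBR, the same numbers when adjusted over the list alone, with Ndufa10 (-1.06 ± 0.10) and Ndufa3 (-1.72 ± 0.19) among the lower ones. Of 16 genes of ATP synthase, 8 were higher and 3 lower (8 and 4 adjusted over the list alone). Atp5e, the epsilon subunit (chromosome 2, 174461072 to 174464105), had 55.1 ± 5.12 FPKM in C57 vehicle and 193.5 ± 20.6 in BTBR vehicle. Atp5g2, a membrane subunit of the same enzyme, had 33.3 ± 2.14 and 3.38 ± 1.36 FPKM, a log2 difference of -3.02 ± 0.22. Complex IV had 4 higher and 6 lower of 12, over all genes and adjusted over the list alone, with Cox7a2 at -2.10 ± 0.19 and Cox6a1 at 1.09 ± 0.14. Complexes II and III had 8 higher and 4 lower of 14 (8 and 5 adjusted over the list alone), with Uqcrq at -1.35 ± 0.14 and Sdhc at 0.94 ± 0.12. None of these 4 nuclear lists was called, with adjusted p of 0.734, 0.487, 0.586 and 0.669 in the order given.

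Among genes of synaptic transmission that passed under vehicle, more were lower than higher in BTBR. Of 20 genes of GABA synthesis, transport and reception, 8 were lower and 0 higher, over all genes and adjusted over the list alone. They included the receptor subunits Gabrb1 (-0.93 ± 0.09) and Gabra5 (-1.13 ± 0.12), Abat (-1.03 ± 0.14), which breaks GABA down, and Slc32a1 (-0.89 ± 0.14), the vesicular GABA transporter. Of 28 genes of synaptic vesicle release, 14 were lower and 2 higher by both counts, over all genes and adjusted over the list alone. Syn1, a synapsin that coats synaptic vesicles (X chromosome, 20860511 to 20921004), had 235.4 ± 14.97 FPKM in C57 vehicle and 68.8 ± 3.48 in BTBR vehicle (log2 -1.76 ± 0.11, adjusted p = 6.79e-07). Rab3a, a vesicle GTPase, stood at -1.0 ± 0.11 and Pclo, a scaffold of the release site, at -0.75 ± 0.11. Camera called both lists lower, with adjusted p = 0.00143 for GABA and 0.00219 for vesicle release. With an estimated correlation, both had an adjusted p of 0.939.

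The postsynaptic density list had 13 lower and 1 higher of 22, over all genes and adjusted over the list alone, with the scaffold genes Dlgap1 (-0.76 ± 0.11), Dlg2 (-0.68 ± 0.10) and Shank1 (-0.79 ± 0.17). Among 28 voltage-gated channels 10 were lower and 2 higher by both counts, over all genes and adjusted over the list alone, including the pacemaker channel Hcn2 (-0.99 ± 0.13) and the sodium channel Scn8a (-0.87 ± 0.13). Camera called both lists lower (adjusted p = 0.0163 and 0.0212), and the adjusted p was 0.939 for each with an estimated correlation. Without BTBR vehicle replicate 1 neither was called, and their highest adjusted p over the alternatives was 0.0637 and 0.155. Of 31 autism risk genes, 10 were lower and 2 higher (the same adjusted over the list alone), among them Arid1b (-0.80 ± 0.09) and Grin2b (-1.01 ± 0.18); the list was not called (adjusted p = 0.118).

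Among 16 interneuron markers 4 were higher and 5 lower, over all genes and adjusted over the list alone. Sst, which encodes somatostatin, had 290.1 ± 28.4 FPKM in C57 vehicle and 783.1 ± 52.2 in BTBR vehicle, and Pvalb, the calcium buffer parvalbumin (chromosome 15, 78191114 to 78206400), had 39.2 ± 4.25 and 113.3 ± 31.9. Npy, neuropeptide Y, went the other way, from 114.3 ± 12.2 to 37.6 ± 11.8 FPKM. Microglial markers also split, with 4 higher and 6 lower of 16 (5 and 6 adjusted over the list alone), for instance P2ry12 at -1.88 ± 0.16 and Aif1 at 0.78 ± 0.12, a median of 0.06 and a mean of -0.20. Upper layer neuron markers had 6 lower and 0 higher of 10, also adjusted over the list alone, with Lamp5 at -0.76 ± 0.14. None of these lists was called, with adjusted p of 0.912 for interneurons, 0.734 for microglia and 0.0824 for upper layer neurons.

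The genes with the largest strain differences under vehicle outside the mitochondrial genome included Eno1b, a gene copy close in sequence to the enolase Eno1. Eno1b (chromosome 18, 48045335 to 48048412) had 11.1 ± 0.869 FPKM in C57 vehicle and 142.3 ± 13.3 in BTBR vehicle (log2 3.56 ± 0.11, adjusted p = 2.92e-09). Eno1 itself, of glycolysis (chromosome 4, 150236721 to 150248879), was lower by a log2 difference of -1.21 ± 0.09, and assignment of fragments between such copies is uncertain. Pttg1, the securin gene of chromosome separation (chromosome 11, 43420250 to 43426251), had 9.63 ± 0.958 FPKM in C57 and 0.646 ± 0.242 in BTBR. Cort, the neuropeptide cortistatin, had 10.1 ± 3.17 and 0.950 ± 0.374 FPKM. Also higher in BTBR were Romo1, a small mitochondrial membrane protein (1.75 ± 0.16), Fbxo2, a ubiquitin ligase subunit for glycoproteins (1.75 ± 0.18), and Ccl17, a chemokine (1.78 ± 0.30). Also lower were Chchd10, a mitochondrial protein (-2.72 ± 0.21), Snrpf, a spliceosome protein (-2.87 ± 0.19), and Atp6v0c, a subunit of the vacuolar proton pump (-2.30 ± 0.22). Snrpf had 0.181 ± 0.041 FPKM in BTBR vehicle, so its value depends on the pseudocount (-4.79 with 0.1, and -5.17 with voom). For each gene of this paragraph the 3 BTBR vehicle libraries lay beyond the 3 C57 vehicle libraries.

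In limma with Benjamini-Hochberg adjustment, 5858 of 13586 genes were called between the strains under vehicle, 3026 higher and 2832 lower in BTBR, and 647 of them by at least 2-fold (289 higher, 358 lower). The groups did not overlap in 53.3% of all genes, where chance gives 10%, and in 5679 of the called genes. Rescaling without the genes of the mitochondrial genome, chosen after seeing the data, moved the median of all genes by -0.118 on the log2 scale and the split to 2029 higher and 3900 lower (34.2% higher, against 51.7%).

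ASIV against vehicle in BTBR mice asked what the compound does in the model strain. All 13 mitochondrial mRNAs rose, by a median of 3.72 on the log2 scale. mt-Nd4 rose from 83.5 ± 16.1 to 1163 ± 73.8 FPKM (log2 3.80 ± 0.27, adjusted p = 1.40e-05), mt-Cytb by 3.89 ± 0.27, mt-Nd2 by 3.75 ± 0.22 and mt-Nd5 by 1.99 ± 0.15. The transfer RNAs mt-Te (5.01 ± 0.29), mt-Tw (4.50 ± 0.32) and mt-Tc (4.48 ± 0.37) rose too, as did mt-Rnr1 (1.24) and mt-Rnr2 (0.77). Here too it was not tested whether transfer RNA counts are separate from those of the mRNAs. The list was called higher (adjusted p = 1.29e-14, with 13 of 13 called over all genes and 13 adjusted over the list alone). With an estimated correlation its adjusted p was 0.439.

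Nuclear OXPHOS genes again moved both ways. Of 36 complex I subunits 14 rose and 12 fell (15 and 13 adjusted over the list alone), with Ndufa3 (1.38 ± 0.19) and Ndufb4 (0.92 ± 0.12) rising and Ndufb7 falling (-0.66 ± 0.09). The complex I list had a median of -0.03, a mean of 0.06 and an adjusted p of 0.813, so its median and mean differ in sign. In ATP synthase 2 of 16 rose and 7 fell (2 and 8 adjusted over the list alone), led by Atp5g2 (2.54 ± 0.22) and Atp5e (-1.30 ± 0.13). Complex IV had 5 rising and 4 falling of 12, by both counts, over all genes and adjusted over the list alone, with Cox7a2 at 1.76 ± 0.19. Complexes II and III had 3 rising and 7 falling of 14 (3 and 8 adjusted over the list alone), with Uqcrq at 1.16 ± 0.14. Their adjusted p was 0.299, 0.457 and 0.471, so none of these lists was called.

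Of 20 genes of GABA signalling 7 rose and 0 fell in BTBR under ASIV, over all genes and adjusted over the list alone, and 13 did not pass. Gabrb1 rose from 4.21 ± 0.226 to 8.26 ± 0.419 FPKM, Slc32a1 by 1.03 ± 0.14, Abat by 1.01 ± 0.14 and Gabra5 by 0.68 ± 0.12. The list was called higher (adjusted p = 0.00798), and its adjusted p was 0.977 with an estimated correlation. In the list of vesicle release 10 rose and 3 fell of 28 (12 and 3 adjusted over the list alone). Syn1 rose by 1.31 ± 0.11 and Rab3a by 0.72 ± 0.11, whereas Syp, the vesicle protein synaptophysin, fell (-0.61 ± 0.11); the list was not called (adjusted p = 0.228). Ribosomal proteins of the cytosol had 27 rising and 11 falling of 79 (30 and 14 adjusted over the list alone), among them Rpl27 (1.54 ± 0.15). That list was called higher (adjusted p = 0.0280, and 0.977 as the adjusted p with an estimated correlation). The ribosomal call was lost without BTBR vehicle replicate 2 and without BTBR ASIV replicate 3, with adjusted p of up to 0.327. Fry, which tests the list against no change and not against other genes, gave an adjusted p of 0.320.

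Among receptors of the other transmitters few genes passed in BTBR under ASIV. Of 22 glutamate receptors 1 rose, Grm5 (0.69 ± 0.14), and 1 fell, by both counts, over all genes and adjusted over the list alone. The muscarinic acetylcholine receptors Chrm1 (0.51 ± 0.11) and Chrm4 (0.63 ± 0.15) rose, as 2 of 8 genes of that list over all genes and adjusted over the list alone. In the monoamine list 3 of 24 rose and 1 fell (1 and 0 adjusted over the list alone). None of these lists was called, with adjusted p of 0.457, 0.501 and 0.670.

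Interneuron markers fell or rose by gene. Pvalb fell from 113.3 ± 31.9 to 33.8 ± 4.77 FPKM and Sst from 783.1 ± 52.2 to 368.2 ± 79.6, while Npy rose by 1.25 ± 0.22 and Dlx5, a transcription factor of interneuron development, by 1.84 ± 0.27. In that list 4 of 16 rose and 3 fell by both counts, over all genes and adjusted over the list alone (adjusted p = 0.512). The microglial genes Cd68 (1.62 ± 0.15) and P2ry12 (1.65 ± 0.16) rose and Trem2 (-0.65 ± 0.09) and Aif1 (-0.76 ± 0.12) fell, with 3 rising and 4 falling of 16 by both counts, over all genes and adjusted over the list alone (median -0.02, mean 0.10, adjusted p = 0.950). Of 17 clock genes 6 rose and 1 fell, also adjusted over the list alone. Nr1d1, a repressor of the clock, rose from 9.96 ± 0.806 to 26.4 ± 4.50 FPKM, and the list was not called by camera (adjusted p = 0.0807) but was by fry (adjusted p = 0.0141). With a pseudocount of 0.1, Dlx5 stood at 2.82, and with voom at 3.04 and Cd68 at 2.55.

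Other genes with the largest rises outside the mitochondrial genome were Chchd10 (2.02 ± 0.21), Snrpf (2.10 ± 0.19), Pcp4, a calmodulin-binding protein of neurons (1.83 ± 0.21), and Ppia, the cyclophilin A gene (1.79 ± 0.21). The largest falls included Stmn3, a neuronal protein that destabilises microtubules (chromosome 2, 181306459 to 181314500), from 1135 ± 221 to 420.6 ± 33.9 FPKM. Cabp1, a neuronal calcium-binding protein, fell by 1.36 on the log2 scale (adjusted p = 2.75e-05), Phf5a, a splicing factor subunit, by 1.39, Dpm3, a subunit of a mannose transferase, by 1.35, and Romo1 by 1.27. Ier5, an immediate early gene, stood at -1.29 ± 0.18. Snrpf stood at 3.88 with a pseudocount of 0.1 and at 4.30 with voom. For each gene of this paragraph the 3 BTBR ASIV libraries lay beyond the 3 BTBR vehicle libraries.

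In limma 3954 of 13586 genes were called for ASIV in BTBR, 1864 higher and 2090 lower, 282 of them by at least 2-fold (207 higher, 75 lower). Groups did not overlap in 39.1% of genes, against 10% by chance, and in 3770 of the called genes. A fit on only the 6 libraries compared called 2258 genes, of which 2230 were among the 3954. After rescaling without mitochondrial genes the median of all genes moved by 0.136 on the log2 scale and 3040 genes rose and 1068 fell (74.0% higher, against 47.1%).

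The same compound in C57 mice asked what ASIV does in the reference strain. No gene passed, so 5 genes per direction with the smallest p are given as values, leaving out pseudogenes and symbols of predicted genes. Higher were Pin4, a prolyl isomerase (0.52 ± 0.11), Pstpip2 (0.47 ± 0.12), Cluap1 (0.36 ± 0.10), Snrpd1, a spliceosome protein (0.45 ± 0.13), and Mdm2, the ligase that turns over p53 (0.29 ± 0.09). Lower were Plxnd1, a semaphorin receptor (-0.52 ± 0.11), Scrt1 (-0.50 ± 0.11), the postsynaptic scaffold Shank3 (-0.52 ± 0.13), Smagp (-0.44 ± 0.12) and Cntnap1, a protein of the axon beside the node of Ranvier (-0.34 ± 0.09). Each had an adjusted p of 1.00.

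In limma 0 of 13586 genes were called for ASIV in C57, with 417 at an unadjusted p under 0.05 where chance gives 679, and 0 with voom as well. The model pools the spread of all 4 groups. The C57 libraries varied less (mean variance 0.0226 under vehicle and 0.0376 under ASIV) than the BTBR ones (0.0642 and 0.05). Pooling makes the test stricter in C57 and looser in BTBR, so the counts of 0 and 3954 are not on an equal footing. Without C57 ASIV replicate 1, 1 gene was called. Groups did not overlap in 13.1% of genes, against 10% by chance. Camera called 9 lists, although 0 of their members were called over all genes. The lower ones were astrocytes (median -0.23, adjusted p = 1.94e-06), microglia (-0.16, 0.000579), postsynaptic density (-0.12, 0.000579), upper layer neurons (-0.22, 0.00234), voltage-gated channels (-0.10, 0.00301), CaMKII (-0.23, 0.00301) and mitochondrial mRNAs (-0.24, 0.0107). The higher ones were deep layer neurons (0.14, 0.0104) and neuropeptides (0.10, 0.0392). Adjusted over the list alone, 1 gene of the postsynaptic list and 1 of the CaMKII list were called, both lower, and 0 in the other 7. With an estimated correlation the adjusted p was 0.679 for astrocytes, microglia, postsynaptic density, upper layer neurons and neuropeptides, and 0.834 for the channels. It was 0.294 for CaMKII, 0.867 for mitochondrial mRNAs and 0.799 for deep layer neurons. Only the astrocyte list kept its call when any 1 library was left out and under every other scaling. Without C57 ASIV replicate 3 the calls of postsynaptic density, channels and upper and deep layer neurons were lost, without C57 vehicle replicate 3 that of microglia, and without C57 vehicle replicate 1 or C57 ASIV replicate 1 that of mitochondrial mRNAs. Neuropeptides lost their call in 9 of 24 alternatives (adjusted p of up to 0.352). CaMKII lost its call after quantile normalization (adjusted p = 0.0740), and with library weights 4 lists were called. With fry, 0 lists were called for ASIV in C57.

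**Figure D2:**
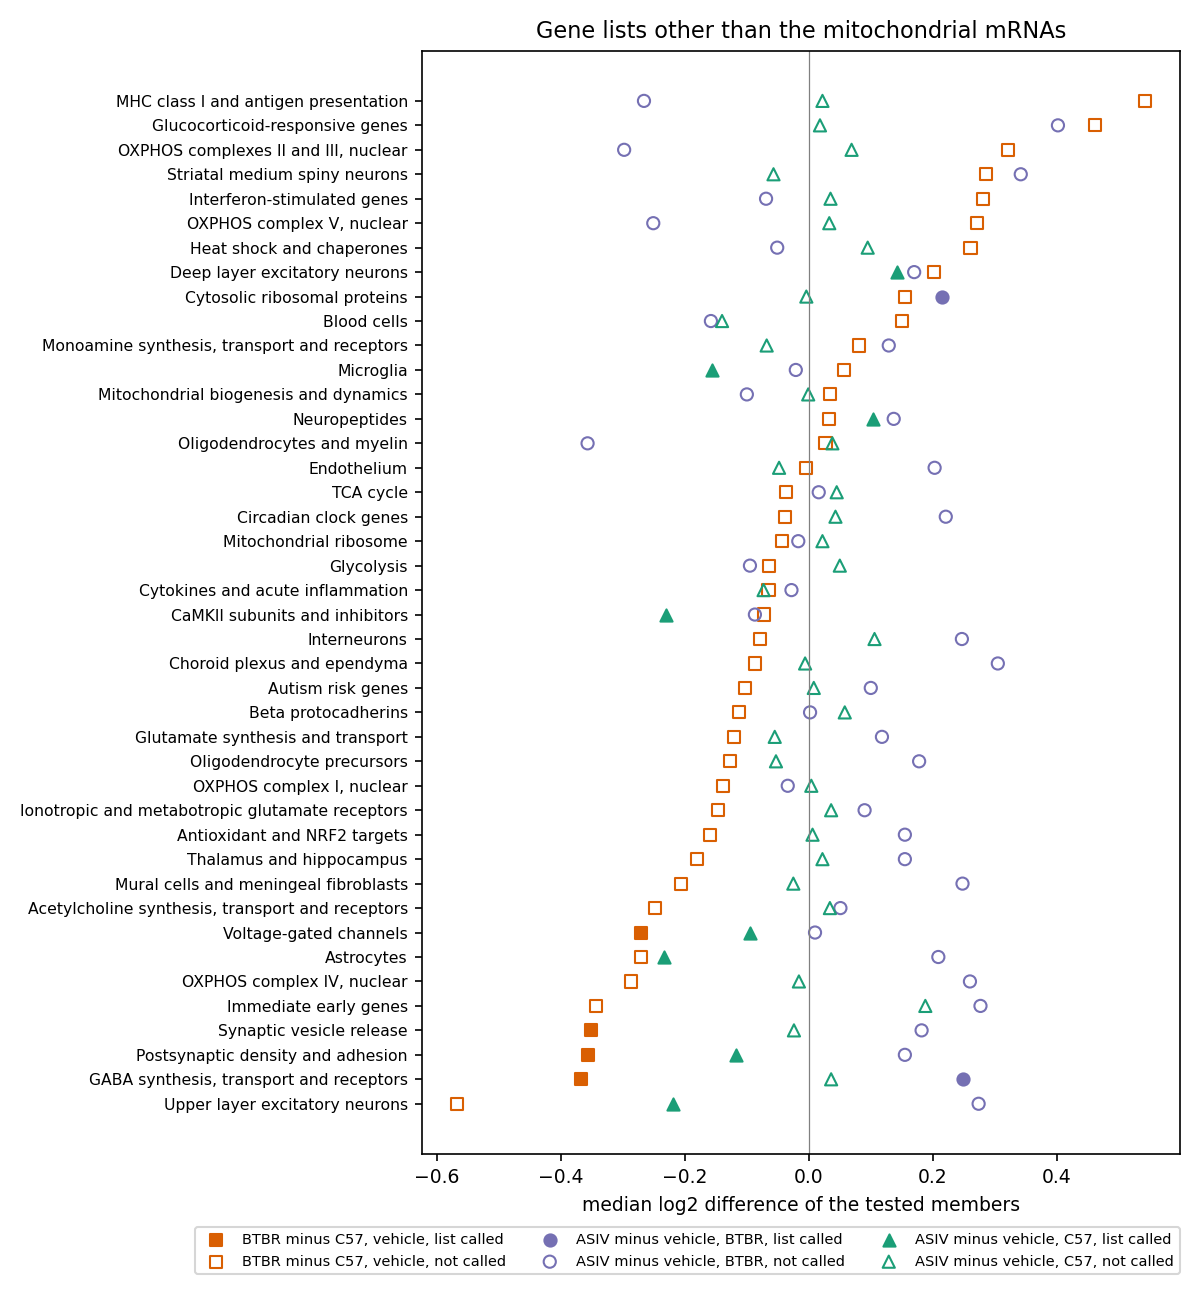
Median log2 difference of the tested members of each gene list other than the mitochondrial mRNAs, for BTBR minus C57 under vehicle (squares), ASIV minus vehicle in BTBR (circles) and ASIV minus vehicle in C57 (triangles). Filled symbols are lists called by camera at a preset correlation of 0.01, and 0 lists are called with an estimated correlation. The GABA list has medians of -0.37 and 0.25 in the first and second comparisons.

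Whether the effect of ASIV differs between strains was tested by the interaction, ASIV in BTBR minus ASIV in C57. Leaving out a pseudogene, the smallest p belonged to mt-Nd2 (4.14 ± 0.30, adjusted p = 5.44e-05), mt-Te (5.59 ± 0.41), mt-Nd5 (2.28 ± 0.21), mt-Nd4 (4.17 ± 0.38) and mt-Cytb (4.13 ± 0.38). In limma 1939 genes were called, 939 higher and 1000 lower, 347 of them by at least 2-fold. Of the 3954 genes called for ASIV in BTBR, 1888 also passed the interaction, all in the same direction (908 higher and 980 lower). The interaction uses the same BTBR libraries, which alone favours the same direction, and no expected count was set against this overlap. The interaction was also fitted with single libraries left out. Its count of genes was 1248, 1166 and 1254 without C57 vehicle replicates 1, 2 and 3 and 1218 without C57 ASIV replicate 1. Rescaling without mitochondrial genes moved the median of all genes by 0.110 and the split to 1164 higher and 513 lower (69.4% higher, against 48.4%).

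To ask whether ASIV moves BTBR genes toward the C57 level, its effect in BTBR was correlated across genes with the mean strain difference over both treatments. The correlation was r = -0.626 (Spearman -0.645, covariance -0.0982), where simulations of unchanged groups with equal spread gave -0.043 to 0.042. The BTBR vehicle libraries varied more than the BTBR ASIV ones (mean variance 0.0642 and 0.05), which leaves a shared error of -0.0024 in the covariance. Simulations with the spread of each group, added after seeing the data, gave -0.141 to -0.0604. Both sets of simulations drew genes independently. For genes that vary together these ranges can be too narrow, so they do not show how far r lies from chance. A shift of the BTBR vehicle libraries alone gives a negative value whatever its origin. With the strain difference under vehicle, which uses the same BTBR vehicle libraries, r was -0.839, against a mean of -0.499 in the simulations. Of the 5858 genes called between strains under vehicle, 3407 were called for ASIV in BTBR, 3392 in the opposite direction (57.9% of the 5858) and 15 in the same. Of the genes higher in BTBR vehicle 1803 fell with ASIV, and of the lower ones 1589 rose. Both comparisons use the BTBR vehicle libraries, which alone favours opposite directions, and no expected count was set against these.

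The strains were also compared under ASIV, in libraries that the vehicle comparison does not use. Eno1b stayed higher in BTBR (3.09 ± 0.11, adjusted p = 1.16e-08), and so did Amd2, a gene copy of an enzyme of polyamine synthesis (1.85 ± 0.16), Pla2g4e, a phospholipase (1.53 ± 0.19), and Scrg1 (1.32 ± 0.14). Lower were Pttg1, with 10.6 ± 0.983 FPKM in C57 ASIV and 0.290 ± 0.060 in BTBR ASIV, Cort (-2.29 ± 0.25), Acp1, a phosphatase (-1.63 ± 0.10), Myo7a, an unconventional myosin (-1.31 ± 0.12), and Eno1 (-1.28 ± 0.09). These genes were taken by the rule repeated after seeing the data, and their groups did not overlap. Gm1866, a processed copy, shares a part of 0.783 of its 31-base words with Acp1. Its mean strain difference over both treatments was 1.36, against -1.69 for Acp1, so assignment of fragments between them is uncertain. With voom, Myo7a stood at -2.77 and Pttg1 at -5.13. Of the 13 mitochondrial mRNAs 1 was called, mt-Nd3 (-2.80 ± 0.26), and the median of the list was -0.37 (camera adjusted p = 0.0168, and adjusted p = 0.972 with an estimated correlation). That call was lost without C57 ASIV replicates 2 or 3 or BTBR ASIV replicate 2, with adjusted p of up to 0.0809.

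**Figure D3:**
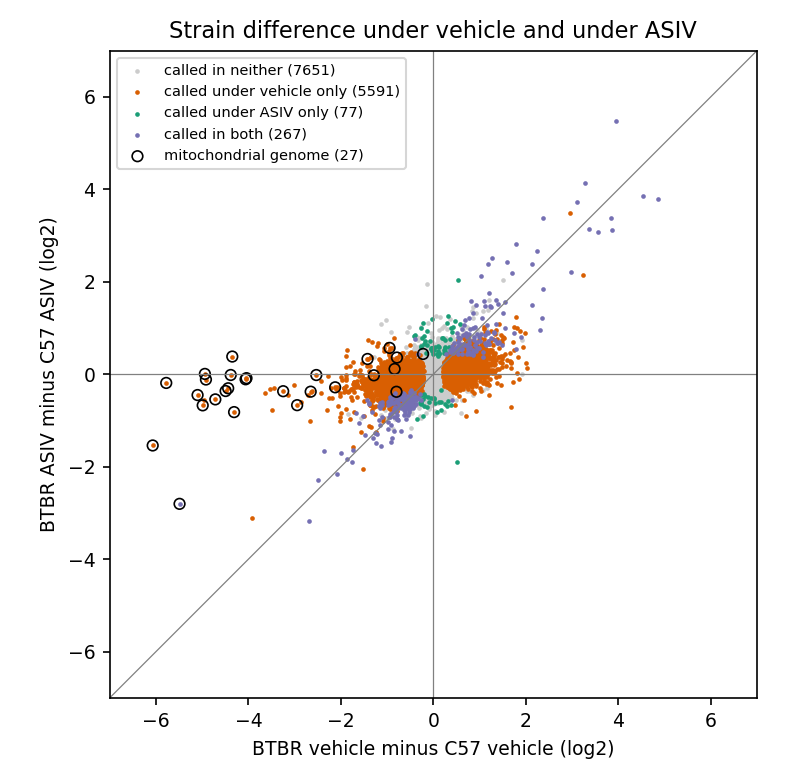
Log2 difference between BTBR and C57 for each tested gene, under vehicle (horizontal axis) and under ASIV (vertical axis). Each point is a gene. Genes called under vehicle number 5858 and under ASIV 344, and r across genes is 0.521.

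In limma 344 genes were called between the strains under ASIV, 178 higher and 166 lower, 78 of them by at least 2-fold. Of these, 267 were among the 5858 called under vehicle, 264 in the same direction and 3 in the opposite one. Over the 5858 genes the median absolute log2 difference was 0.54 under vehicle and 0.16 under ASIV; they were selected by the vehicle comparison, and over all 13586 genes it was 0.29 and 0.14. Across genes the strain differences under vehicle and under ASIV had r = 0.521. The count varied with single libraries: 99 without C57 ASIV replicate 2, 108 without C57 ASIV replicate 3, 128 and 162 without BTBR ASIV replicates 3 and 1, and 644 and 576 without BTBR vehicle replicates 2 and 3. It was 1546 with library weights, which included 343 of the 344.

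Glucocorticoid-responsive genes formed a list called higher in BTBR under ASIV (adjusted p = 4.36e-07), with 3 of 15 called over all genes and 8 adjusted over the list alone. Tsc22d3, a glucocorticoid-induced leucine zipper (0.92 ± 0.17), Sult1a1, a sulfotransferase (1.59 ± 0.29), and Pdk4, a kinase that holds back pyruvate dehydrogenase (1.10 ± 0.21), were higher. Tsc22d3 kept its direction but lost its call in 3 alternatives, Sult1a1 in 4 and Pdk4 in 4, with adjusted p of up to 0.0749, 0.0807 and 0.0905. Under vehicle camera did not call this list, yet some members were called there too. Tsc22d3 (1.12 to 1.55 over the alternatives), Fkbp5 (0.71 to 1.32) and Zbtb16 (0.57 to 0.91) were higher in BTBR vehicle. Errfi1 was lower (-0.59 to -0.29). Ribosomal proteins were higher as a list (adjusted p = 8.86e-09), with 5 higher of 79 over all genes and 21 higher and 1 lower adjusted over the list alone. Synaptic vesicle genes were lower as a list (adjusted p = 0.000206), with 0 of 28 called over all genes and 6 lower adjusted over the list alone; Snap25 stood at -0.63 ± 0.17 and Syt1 at -0.48 ± 0.13. The adjusted p was 0.972 for each of these 3 lists with an estimated correlation. Oligodendrocyte precursors and astrocytes were called higher (adjusted p = 0.0189 and 0.0283) and voltage-gated channels and glycolysis lower (0.0183 and 0.0188), each with an adjusted p of 0.972 with an estimated correlation. Over all genes these lists had 0 of 12, 2 of 14, 0 of 28 and 1 of 18 called, and 5, 2, 0 and 1 adjusted over the list alone. Each lost its call in 1 to 4 alternatives, with adjusted p of up to 0.138, 0.258, 0.113 and 0.0768. With fry, 0 lists were called between strains under ASIV.

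CaMKII, the calcium/calmodulin-dependent kinase of synapses, and its inhibitor proteins were examined because the series title names Camk2n2. Camk2n2 (chromosome 16, 20619215 to 20621287) had 163.6 ± 10.3 FPKM in C57 vehicle, 128.2 ± 19.8 in C57 ASIV, 222.1 ± 69.2 in BTBR vehicle and 153.2 ± 12.7 in BTBR ASIV. It did not pass in any comparison over all genes: its log2 difference was -0.49 ± 0.18 for ASIV in BTBR (adjusted p = 0.0529) and -0.36 ± 0.18 for ASIV in C57 (adjusted p = 1.00). Between strains it was 0.40 ± 0.18 under vehicle (adjusted p = 0.0871) and 0.26 ± 0.18 under ASIV (adjusted p = 0.435). The interaction stood at -0.14 ± 0.25 (adjusted p = 0.764). In an exact two-sided permutation test of 3 against 3 libraries, p was 0.1, the smallest that this design allows, for ASIV in either strain and for the strains under vehicle, and 0.3 for the strains under ASIV. The value for ASIV in BTBR passed the threshold under 2 planned settings, a filter of FPKM 5 (adjusted p = 0.0405) and the replicate block (0.0443). It also passed without C57 ASIV replicate 1 (0.0496), BTBR vehicle replicate 1 (-0.59, 0.0423) and BTBR vehicle replicate 2 (-0.64, 0.0212). Over all alternatives its adjusted p ran from 0.0212 to 0.172, and without BTBR vehicle replicate 3 it was -0.25.

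Camk2n1, a related inhibitor (chromosome 4, 138454314 to 138460123), was higher in BTBR than in C57 under vehicle (0.66 ± 0.14, adjusted p = 0.00232). With ASIV it fell in BTBR from 1207 ± 180 to 754.4 ± 83.2 FPKM (log2 -0.67 ± 0.14, adjusted p = 0.00365). Camk2a, the main alpha subunit of the kinase in forebrain (chromosome 18, 60925618 to 60988152), was lower in BTBR under vehicle (-0.66 ± 0.12, adjusted p = 0.000736) and rose with ASIV in BTBR from 387.4 ± 40.4 to 555.6 ± 25.9 FPKM (0.52 ± 0.12, adjusted p = 0.00543). Its interaction was 0.93 ± 0.16 (adjusted p = 0.00457), and that of Camk2n1 was -0.33 ± 0.20 (adjusted p = 0.295). For ASIV in C57, Camk2a stood at -0.41 ± 0.12 and Camk2n1 at -0.35 ± 0.14 (adjusted p = 1.00 for each), so that part of the Camk2a interaction comes from the C57 libraries. Camk2b stood at -0.05 ± 0.10 between strains under vehicle and at -0.01 ± 0.10 for ASIV in BTBR, with signs that changed between scalings. In the list of 6 CaMKII genes 1 was higher and 1 lower between strains under vehicle, the same adjusted over the list alone (median -0.07, mean 0.02, adjusted p = 0.924). For ASIV in BTBR 1 rose and 1 fell over all genes, with 1 and 2 adjusted over the list alone (adjusted p = 0.683 for the list). Camk2n2 was the gene added by the count over the list alone. Itpr3, the tested gene of the BTBR background loci, had a log2 difference of -0.13 ± 0.13 between strains under vehicle (adjusted p = 0.444) and 0.04 ± 0.13 for ASIV in BTBR (adjusted p = 0.819).

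**Figure D4:**
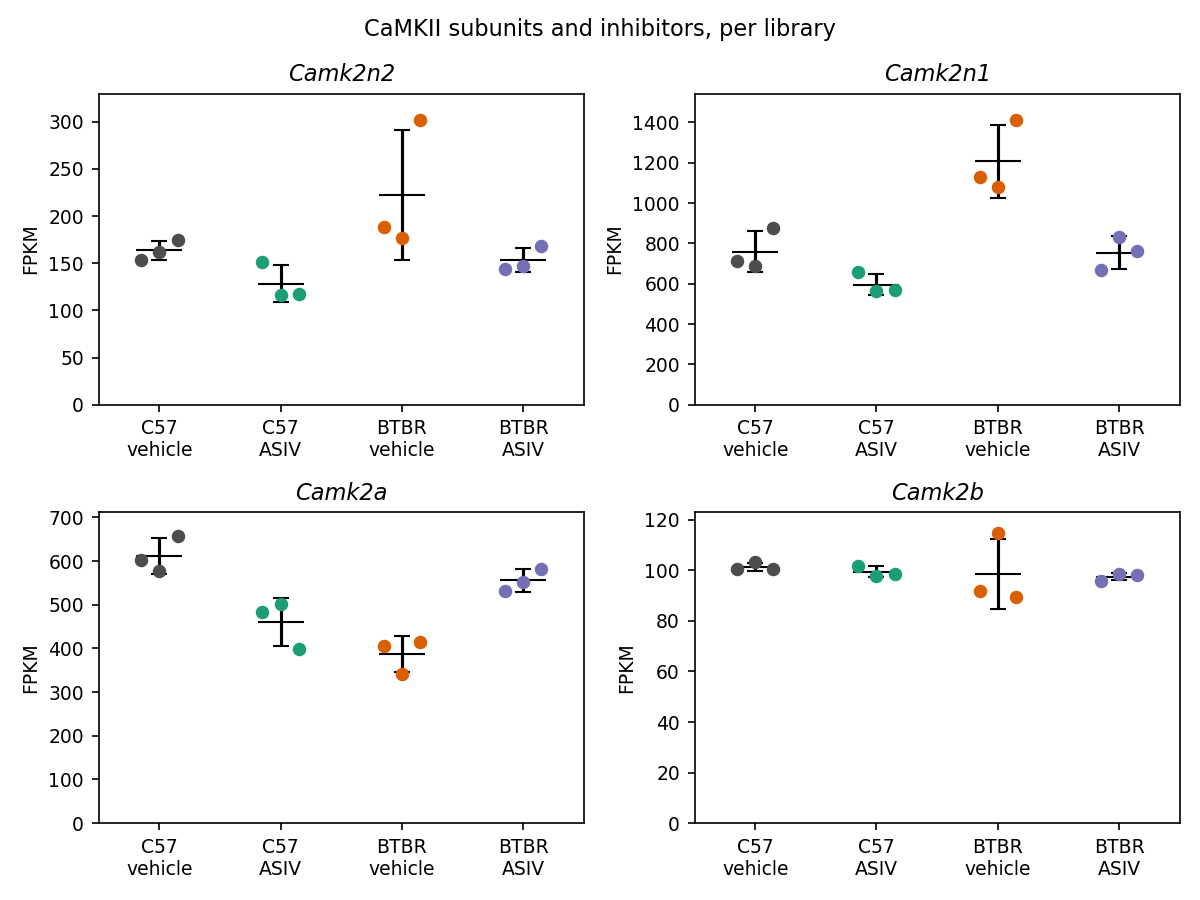
FPKM of the CaMKII inhibitors Camk2n2 and Camk2n1 and of the kinase subunits Camk2a and Camk2b, per library, in the 4 groups. Points are libraries, and bars give the mean and SD of 3 libraries. In BTBR, Camk2n1 had a mean of 1207 under vehicle and 754.4 under ASIV, and Camk2a 387.4 and 555.6.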

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

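The tests of a strain variant and of a lower content of all mitochondrial RNA, and the fits with voom, with a GC and length trend removed and without mitochondrial genes, were chosen only after the result was seen. The results here were picked out because the effect of ASIV differed between BTBR and C57 mice by the interaction test, which 1939 genes passed. Groups of 3 are too small for a test of single libraries that stand apart.

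Among gene lists, the median interaction was 3.958 for mitochondrial mRNAs (13 of 13 called, also adjusted over the list alone; adjusted p = 1.21e-16, and adjusted p = 0.316 with an estimated correlation). It was 0.275 for GABA genes (4 of 20 called, 4 adjusted over the list alone; adjusted p = 0.0146) and 0.291 for the postsynaptic density (5 of 22, 6 adjusted over the list alone; 0.0241). It was 0.438 for astrocytes (2 of 14, 5 adjusted over the list alone; 0.0266), 0.380 for upper layer neurons (2 of 10 by both counts; 0.0266) and 0.216 for ribosomal proteins of the cytosol (20 higher and 8 lower of 79, 24 and 11 adjusted over the list alone; 0.0309). These 5 lists had an adjusted p = 0.906 with an estimated correlation, and all but GABA lost their call in 3 to 5 other alternatives. With fry only the mitochondrial mRNAs were called (adjusted p = 0.000425).

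Among named genes of the mitochondrial genome the log2 interaction was 5.59 for mt-Te, 4.95 for mt-Ty, 4.81 for mt-Tc, 4.73 for mt-Tw, 4.65 for mt-Atp6, 4.53 for mt-Nd4l, 4.32 for mt-Tn, 4.17 for mt-Nd4, 4.14 for mt-Nd2, 4.13 for mt-Cytb, 3.95 for mt-Tl1 and 2.28 for mt-Nd5. Among nuclear genes it was higher in BTBR for Atp5g2 (2.79), Chchd10 (2.28), Snrpf (2.26), Dlx5 (1.81, and 2.94 with voom), Cox7a2 (1.78), Pcp4 (1.77), Ppia (1.76), Camk2a (0.93), Scrt1 (0.72) and Shank3 (0.62). Shank3 lost its call in 12 of 23 alternatives, with adjusted p of up to 0.114. For most genes of this paragraph the interaction was not run under the alternatives. It was lower for Pin4 (-0.57), Mdm2 (-0.59), Snrpd1 (-0.95), Cabp1 (-1.0), Cluap1 (-1.04), Epb41l4aos (-1.15), Romo1 (-1.23), Atp5e (-1.24), Yjefn3 (-1.30), Dpm3 (-1.37), Ier5 (-1.39), Phf5a (-1.39), Stmn3 (-1.56), Pvalb (-1.70), Snrpe (-1.88) and Snora31 (-2.39). Scrt1, Shank3, Pin4, Mdm2, Snrpd1 and Cluap1 were named for their small p for ASIV in C57, where none was called. That comparison is part of the interaction, which favours a large value. Shank3 went from 52.78 to 36.9 FPKM with ASIV in C57 and from 50.89 to 54.55 in BTBR. Genes named for ASIV in BTBR were likewise chosen on the other part.

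The first pattern weighed is the low level of mitochondrial mRNAs in BTBR vehicle libraries. A strain variant of the mitochondrial genome would lower them under ASIV too, where their median strain difference was -0.37. The exception was mt-Nd3, called lower with 13.25 FPKM in BTBR ASIV and 100.9 in C57 ASIV. The median does not speak for mt-Nd3. A lower content of all mitochondrial RNA would lower the 2 ribosomal RNAs alike, which fell less by 3.6 on the log2 scale. That comparison holds only if RNA selection treated ribosomal RNAs alike in all groups. Since the selection is not known, a lower content is not excluded. Fragments shared between annotated genes do not account for the whole of the low level. The 4 mRNAs with under 10% shared 31-base words had a median of -3.49. For selection of polyadenylated RNA, 32 nuclear RNAs assumed from class or symbol to lack a poly(A) tail had a median of 0.02 (SE 0.26). The lack of a tail was not checked. The median met the bound set for no effect, but 5 members were higher and 6 lower (SD 1.16). That bound was wrong for members that go both ways, so this median decides nothing. Library batch cannot be told apart from group, since the labels give none, and a biological difference by strain and treatment stays open as untested.

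The next pattern is the breadth of the difference between BTBR and C57 vehicle. With a GC and length trend removed 6061 genes were called, with 94.4% of the earlier calls kept, and scaled without mitochondrial genes 5929 were called, so neither accounts for the whole of it, although the latter moved the split of higher and lower genes. Genes with at least 50% shared 31-base words differed from those with under 10% by -0.023 (SE 0.048) in median. This argues against a general loss of shared fragments in BTBR vehicle. Fragments that move between a gene and its copy lower the former as they raise the latter. Such movement can leave the class median unchanged, so it stays open. Library batch cannot be told apart from group here either, and a biological difference stays open.

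The last pattern is the strain difference at processed copies of genes. Of 501 tested copies, 34 were called the same way in both strain comparisons, against 199 of 12144 protein-coding genes. Of 33 copies called in both strain comparisons with a tested parent gene, 57.6% had a parent that differed the opposite way. The 95% CI of 39.2 to 74.5 includes 50%. The share lies between the bounds set beforehand for and against movement of fragments. Where the parent was itself called for the mean strain difference, 15 differed the opposite way and 10 the same way. The copies Gm4735 and Gm5855 were scored against Eno1b (mean strain difference 3.32), itself a gene copy, and so count as the same way. Eno1 went the other way. Some copies also share a parent, which the interval treats as independent. Movement of fragments between gene and copy and a true strain difference cannot be told apart by this share.

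For the count of calls, other splits of the 6 libraries compared were tried. With 10 splits the share cannot fall below 0.05, so the splits are too few. Only 1 of 10 splits reached the 3954 genes for ASIV in BTBR (highest other 16), 1 of 10 the 5858 between strains under vehicle (highest other 0) and 1 of 10 the 344 between strains under ASIV (highest other 5). For ASIV in C57 all 10 of 10 reached the count of 0. For the interaction, 3 of 100 splits of treatment within strain called as many genes, the real one among them, with 2077 as the highest other. The 7 drawn splits that kept the BTBR groups apart called 1403 to 2077, and 2 of these reached the real count. The 92 that mixed the BTBR groups called at most 9. The count thus follows the BTBR grouping, and these splits do not show that it depends on the C57 grouping.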

How the results depend on the processing

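The fits with voom, with a GC and length trend removed and without mitochondrial genes were chosen only after the results were seen. Of 460 named gene results, 446 were called, and 332 of these kept their call and direction in every alternative, while 114 lost the call in at least 1. All 31 list calls kept their direction, and 0 lists were called with an estimated correlation in each of the 5 comparisons (0, 0, 0, 0 and 0). For ASIV in BTBR, ASIV in C57, the strains under vehicle, the strains under ASIV and the interaction, camera called 3, 9, 5, 8 and 6 lists, fry 4, 0, 8, 0 and 1, and fry for changes in either direction 36, 0, 38, 15 and 30. The log2 scale and a depth of 16166328 to 18660039 fragments limit what is seen at low FPKM. Where values moved as given below, the cause was not tested.

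The correlation of reversal was -0.626, and -0.585 with pseudocount 0.1, -0.666 with a filter of FPKM 5, -0.567 rescaled to TPM, -0.572 with voom, -0.530 rescaled without mitochondrial genes and -0.839 with the vehicle strain difference, which shares libraries. Lists called for ASIV in BTBR were 8 after quantile normalization, and between strains under vehicle 8 in a fit on only the 2 groups compared. That kind of fit called 2258 genes for ASIV in BTBR, with fewer libraries and without the lower spread of the C57 ones. With library weights ASIV in C57 had 4 lists and the strains under ASIV had 1546 genes. Camk2n2 for ASIV in BTBR stayed at -0.49 but passed the threshold with a filter of FPKM 5 and with the replicate block. Camk2b between strains under vehicle was 0.01 rescaled to TPM, and for ASIV in BTBR 0.10 after quantile normalization, 0.04 with library weights, 0.04 with voom and 0.15 rescaled without mitochondrial genes.

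With 1 library left out, genes called ran from 3076 to 4034 for ASIV in BTBR, 0 to 1 for ASIV in C57, 4543 to 5925 between strains under vehicle, 99 to 644 under ASIV and 1166 to 2195 for the interaction. Lists called ran from 2 to 6, 7 to 10, 3 to 6, 6 to 11 and 3 to 9 in that order. The reversal ran from -0.667 to -0.506. Camk2n2 ran from -0.64 to -0.25 for ASIV in BTBR, -0.48 to -0.29 for ASIV in C57, 0.16 to 0.54 between strains under vehicle, 0.20 to 0.39 under ASIV and -0.28 to 0.11 for the interaction. Camk2b ran from -0.16 to 0.02 between strains under vehicle and -0.07 to 0.10 for ASIV in BTBR, and Itpr3 from -0.04 to 0.10 for ASIV in BTBR. Voom called 4087, 0, 5823, 405 and 2077 genes, and the fit with a GC and length trend removed 4350, 0, 6061, 408 and 2342. With the replicate number as a block the counts were 4013, 0, 5808, 415 and 1862; r ran from -0.172 to 0.279 in pairs of libraries with the same number and from -0.370 to 0.225 in other pairs, and not every library correlated best with its own number.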

Other observations

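Of the tests in this part, the fits with voom and with a GC and length trend removed were chosen only after the result was seen. Genes of MHC class I and antigen presentation had 9 of 17 higher and 1 lower in BTBR than in C57 under vehicle, over all genes and adjusted over the list alone. B2m, the light chain of MHC class I, was the lower one (-1.75 ± 0.16), and H2-Q4 (0.97 ± 0.16) and Tap2, a peptide transporter (0.62 ± 0.11), were higher. With ASIV in BTBR, B2m rose (1.34 ± 0.16) and 6 of the 17 fell by both counts, among them Tap2 (-0.57 ± 0.11). Camera called the list in neither comparison (adjusted p = 0.112 and 0.115).

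Genes of the mitochondrial ribosome had 20 higher and 25 lower of 77 under vehicle (20 and 26 adjusted over the list alone), with Mrpl42 at -2.01 ± 0.17, Mrps11 at -1.49 ± 0.13 and Mrpl52 at 1.43 ± 0.14. With ASIV in BTBR 17 rose and 16 fell (18 and 18 adjusted over the list alone), with Mrpl42 at 1.43 ± 0.17 (2.22 with voom) and Mrpl51 at -0.88 ± 0.11. In the TCA cycle list 2 were higher and 6 lower of 19 under vehicle by both counts, over all genes and adjusted over the list alone, among them Cs, citrate synthase (-0.56 ± 0.09), and Idh3g, a subunit of isocitrate dehydrogenase (-0.72 ± 0.10). Among chaperones under vehicle 8 of 18 were higher and 3 lower (8 and 4 adjusted over the list alone), with the ER stress gene Creld2 at 0.93 ± 0.10 and the heat shock gene Hspa1a at -1.08 ± 0.14 (-1.71 with voom). None of these lists was called (adjusted p of 0.734 and 0.810 for the ribosome, 0.672 for the TCA cycle and 0.686 for chaperones).

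As values, 12 striatal markers had a median log2 difference of 0.29 (SE 0.16) between strains under vehicle and 0.34 for ASIV in BTBR, with 0 called. Of 7769 genes without exon overlap with another gene 43.0% were called between strains under vehicle, and of 4362 with overlap 44.3%. With a GC and length trend removed the mitochondrial mRNAs had a median of -4.26 between strains under vehicle. Spearman correlations of GC content with the log2 difference over 12131 genes were -0.110 for ASIV in BTBR, -0.397 for ASIV in C57, 0.121 for the strains under vehicle and 0.276 under ASIV.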
